A study of Mus musculus with 15 samples.

How the data were processed

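Poly-A selected RNA from mouse ovarian tissue was measured by sequencing in 15 libraries, 5 from each of 3 groups. The mice were 8-week-old female C57BL/6 animals, and per the labels 6 cages held 5 mice each. VCD (4-vinylcyclohexene diepoxide), an ovotoxic chemical that destroys small ovarian follicles, was injected into the abdomen daily for 15 days at 160 mg/kg in sesame oil. The control group received sesame oil. The group names give 15 or 30 days for the VCD groups, whereas the time given with each sample is 15 days for all of them. The day on which the control ovaries were taken is not given separately, so the comparison of day 30 with control also holds any difference in age or time.

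The deposited table of counts gives raw read counts per gene, made by the authors without normalization. The authors name fastp, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and the genome build GRCm39. The start and end coordinates coincided for 98.3% of the 54495 gene IDs shared with GENCODE M21, an annotation of the earlier build GRCm38, so coordinates are printed as the count table gives them. The table held 55663 entries, of which 54532 had an Ensembl ID and 1131 were loci without a symbol from the authors' own assembly. These loci took from 0.231% to 0.381% of the counts of a library. For 27 symbols turned into dates, the Ensembl ID was used. The deposited FPKM values were made by the authors, and above 100 counts each one equalled the count over gene length and a constant per library. That constant was 0.893 to 1.09 times the total count, and how it was set is not stated. The sequencing strand protocol is not stated.

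Total counts ranged from 15021246 to 18035127 per library. Intervals for ratios of low counts are exact 95% intervals on counts summed over the 5 libraries of a group. They cover counting error only and leave out variation between mice. The reads carry no molecular identifiers. With 1 to 3 counts in a group, the ratio of summed counts scaled by library size is given in place of a fitted fold.

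Genes were tested with the edgeR quasi-likelihood F test (R 4.3.3, edgeR 4.0.16), two-sided, on all 15 libraries with TMM normalization and no covariate. The filterByExpr filter, with a minimum count of 10 and a minimum total of 15, left 17462 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 folds were taken from the fold and its F statistic. Levels are TMM-normalized library-scaled counts (CPM, the count scaled to a fixed total per library), given as mean ± SD. The recovery was tested on simulated data with 5 libraries per group: 2-fold changes were called for 56%, 63% and 57% of changed genes and 4-fold changes for 84%, 82% and 88%, in the order day 15 against control, day 30 against control and day 30 against day 15. The changed genes were drawn only from genes above a minimum expected count, so these shares do not cover tested genes with fewer counts.

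The groups, comparisons, tests, gene lists and rule for named genes were chosen before the data were examined. The 30 lists were oocyte, small-follicle germ cell, granulosa cell, theca cell, corpus luteum, steroid hormone synthesis, cholesterol synthesis, ovulatory response, epoxide and glutathione detoxification, NRF2 targets, p53 targets, apoptosis machinery, DNA repair, cell cycle, KIT-PI3K-FOXO3 follicle activation, extracellular matrix, smooth muscle and pericyte, endothelium, macrophage, neutrophil, lymphocyte, inflammatory cytokine, interferon response, surface epithelium and mesothelium, oviduct epithelium, adipocyte, red blood cell, oxidative phosphorylation, immediate early and circadian clock. Some genes stand in more than 1 list, for example 9 of 17 members of the steroid hormone synthesis list. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 90 tests of 30 lists and 3 comparisons, and again with an estimated correlation. Camera asks whether the genes of a list moved against all other tested genes. Each list also has a score per library, the mean of log2(CPM + 0.5) over its genes, whose group difference was tested by exact two-sided permutation. With 5 libraries against 5, the smallest p of that test is 0.00794.

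Named genes were fixed by a rule. It took 10 genes whatever their values (Gdf9, Zp3, Ddx4, Amh, Fshr, Cyp19a1, Star, Cyp17a1, Ephx1 and Cdkn1a). Per comparison it added the 4 largest folds up and the 4 largest folds down among called genes with a mean log2 CPM of at least 1 and no overlap between groups. It also added the 2 members with the smallest p of each list that passed or had a called member. A gene chosen outside this rule is said to be so. 2 genes among the flagged results, 1 outlier and 1 difference between day 30 and day 15, are not reported here, and the counts of flagged results include them.

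Genes called in both comparisons against the same control group were counted. The count was set beside 20 simulations of unchanged groups, the overlap of independent lists, and 20 splits of the 5 controls. Alternatives were DESeq2 size factors in edgeR, upper-quartile normalization, no filter, a mean of at least 1 CPM, the DESeq2 Wald test (1.42.0), limma-voom with quality weights and only the compared groups. Further alternatives were a replicate block, log2(FPKM + 0.1) and log2(FPKM + 1) with limma-trend at a mean FPKM of at least 0.1, a fold of at least 2, an adjusted p under 0.01, and leaving out each library. A further 3 alternatives were added after seeing the data, namely leaving out the 5 libraries with Ovgp1 above 100 CPM together, a covariate of log2 CPM of Ovgp1, and a covariate of each library's correlation of expression with gene length. No library was left out of the reported values, and no pair of libraries within a group was a duplicate by a chi-square comparison of counts (lowest value per gene 8.15).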

Results

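Ovarian transcriptomes were compared between control mice, mice named for day 15 of VCD and mice named for day 30, with 5 libraries in each group. VCD was given for 15 days, so that day 30, if counted from the first injection, follows a time without injections. Total counts per library were 15471307 to 17821363 in control, 15442599 to 17050476 at day 15 and 15021246 to 18035127 at day 30. The study asked how the ovarian transcriptome changes at both times in a mouse model of premature ovarian insufficiency.

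The first principal component held 35.2% of the variance of all tested genes and placed all 5 day 30 libraries apart from all control libraries. Ovgp1, which encodes the oviduct secretory glycoprotein, stood at 5384 CPM in control 1, 1932 in control 3, 848 in VCD day 15 library 3, 473 in VCD day 30 library 2 and 130 in control 2. It stood between 1.20 and 11.9 CPM in the other 10 libraries. The correlation of expression with gene length, across genes and relative to the mean library, was 0.313 in control 1, 0.314 in VCD day 15 library 1 and −0.354 in VCD day 30 library 1, and between −0.203 and 0.109 in the others. Mitochondrial transcripts took 6.98 ± 1.63% of counts in control, 8.07 ± 3.27% at day 15 and 5.18 ± 1.61% at day 30 (mean ± SD, n = 5). The exact two-sided permutation p values for this share were 0.556 for day 15 against control, 0.103 for day 30 against control and 0.119 for day 30 against day 15.

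**Figure D1:**
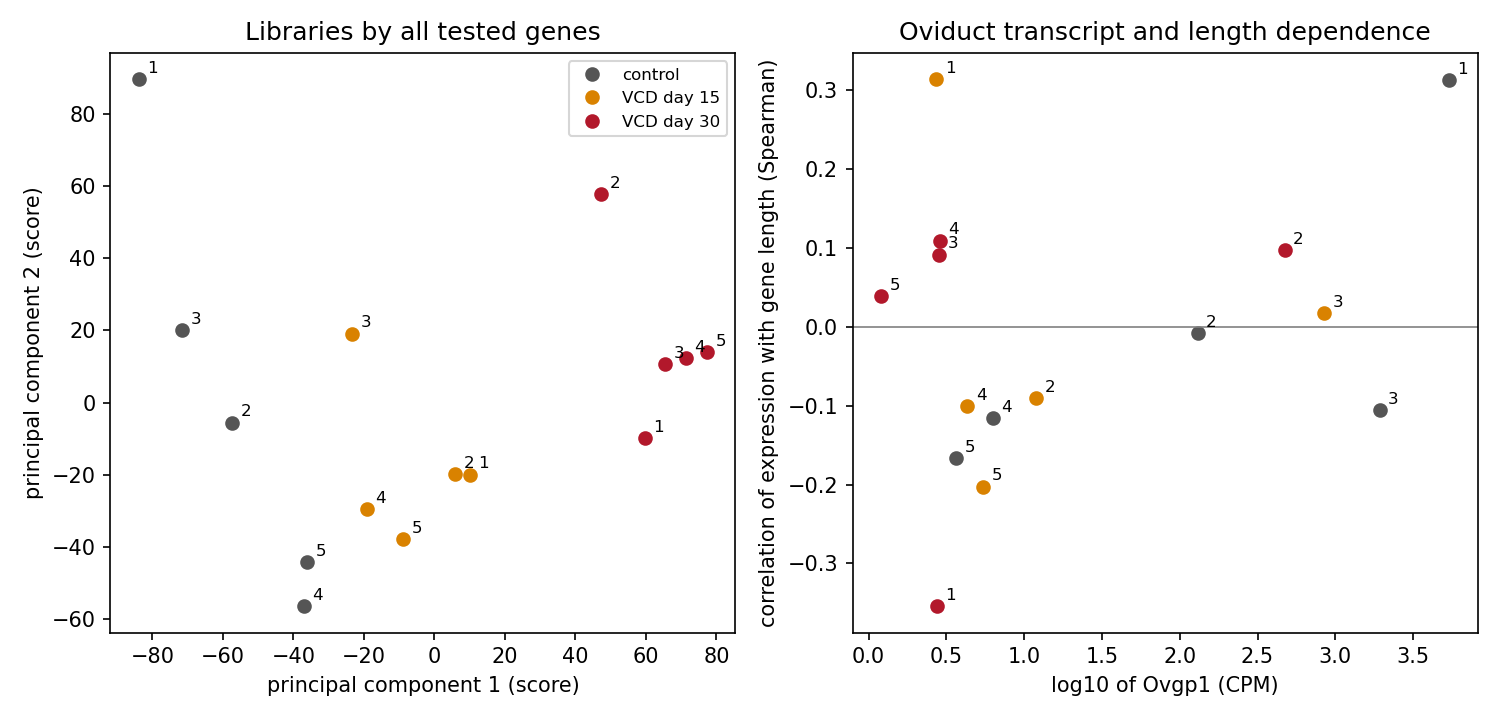
Each point is 1 library, numbered by replicate. The first panel plots principal component 1 against component 2 (35.2% and 18.3% of variance), and the second plots the log10 CPM of Ovgp1 against the Spearman correlation of expression with gene length across genes. The 5 day 30 libraries lie apart from the controls on component 1, and control 1 has both the highest Ovgp1 level and a length correlation of 0.313.

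The first comparison asked what had changed at day 15 of VCD. Genes of oocytes were among those that fell. Gdf9, a growth factor secreted by oocytes (ENSMUSG00000018238, chromosome 11, 53431023 to 53437904, plus strand), fell from 69.3 ± 6.41 CPM in control to 9.79 ± 6.94 CPM, a log2 fold of −2.82 ± 0.39 (SE, n = 5 and 5, adjusted p = 0.00307). Nobox, an oocyte homeobox transcription factor (ENSMUSG00000029736, chromosome 6, 43303674 to 43309554, minus strand), fell from 10.9 ± 2.60 to 1.15 ± 0.662 CPM (log2 fold −3.23 ± 0.50, adjusted p = 0.00537). Among genes of granulosa cells, which surround the oocyte, Amh, a hormone of growing follicles (ENSMUSG00000035262, chromosome 10, 80805243 to 80807648, plus strand), fell from 169 ± 36.4 to 36.8 ± 19.4 CPM (log2 fold −2.20 ± 0.39, adjusted p = 0.0133). In all, 175 of 17462 genes were called, of which 166 were lower and 9 higher.

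The oocyte list had 17 of its 24 tested members called lower, and 24 when adjusted over the list alone, with none higher. Its median log2 fold was −2.46 and camera passed it (adjusted p = 1.89e-49, and adjusted p = 0.0226 with an estimated correlation). Examples were Zp2 and Zp3, proteins of the egg coat, and Nlrp5 and Ooep, of the maternal complex under the egg membrane. Zp2 fell by 3.64 on the log2 scale and Zp3 by 3.02, from 43.0 ± 21.7 to 5.28 ± 4.01 CPM. The log2 fold was −3.61 for Nlrp5 and −2.46 for Ooep. The small-follicle germ cell list had 4 of 10 members called lower, and 8 when adjusted over the list alone. Its median was −1.96 (adjusted p = 1.92e-16, and adjusted p = 0.0191 with an estimated correlation). Elavl2, which encodes an RNA-binding protein, had a log2 fold of −1.85 ± 0.28 in this list, whereas the germ cell helicase Ddx4 was not called (−0.92 ± 0.35, adjusted p = 0.264). The Zp3 call ended when any 1 of 10 libraries was left out: control 2, 3, 4 or 5, day 15 library 1, 2, 3 or 5, or day 30 library 3 or 5, with adjusted p from 0.0576 to 0.147. It also ended at a mean of at least 1 CPM (adjusted p = 0.0553) and with the DESeq2 Wald test (0.0603). The Zp2 call ended without control 2 or 3 or without day 15 library 2 or 3 (adjusted p 0.0549 to 0.0819), the Nlrp5 call without day 15 library 2 (0.0579) and the Amh call without the same library (0.0621).

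The granulosa cell list had 3 of 25 members called lower, and 4 when adjusted over the list alone, with none higher. Its median log2 fold was 0.07 and its mean −0.12, while camera passed it as lower (adjusted p = 0.0365, and adjusted p = 0.734 with an estimated correlation). The monoamine transporter gene Slc18a2 fell from 167 ± 63.2 to 38.9 ± 18.4 CPM (log2 fold −2.10 ± 0.32). The follicle-stimulating hormone receptor Fshr (0.07 ± 0.46, adjusted p = 0.973) and the aromatase gene Cyp19a1 (1.31 ± 0.82, adjusted p = 0.585) were not called. The granulosa median was −0.23 without the 5 libraries with high Ovgp1, with 19 of 25 members below 0 (adjusted p = 1.77e-05), and −0.20 with Ovgp1 as a covariate (adjusted p = 0.000152). The cell cycle list passed as lower with a median of −0.43 (adjusted p = 1.17e-08, and adjusted p = 0.321 with an estimated correlation). Its median was −0.69 without these 5 libraries, with all 30 members below 0. It had 1 of 30 members called, the spindle checkpoint kinase Bub1b (−0.70 ± 0.15), and 4 when adjusted over the list alone. The DNA repair list also passed as lower, with a median of −0.13, 0 of 25 members called and 1 adjusted over the list alone (adjusted p = 0.0144, and adjusted p = 0.430 with an estimated correlation). The Bub1b call ended without control 2, 4 or 5, day 15 library 2, 3 or 4, or day 30 library 3, 4 or 5 (adjusted p 0.0594 to 0.132). The granulosa call ended without control 2, 4 or 5, day 15 library 1, 2 or 3 or day 30 library 3 (0.058 to 0.429). It also ended with upper-quartile normalization (0.0530), with no filter on low counts (0.0623), with only the compared groups (0.0719) and with the FPKM values (median −0.05 and adjusted p = 0.146 for log2(FPKM + 0.1), −0.05 and 0.175 for log2(FPKM + 1)). The DNA repair call ended without control 4 or 5 or day 15 library 2, 3 or 5 (0.0503 to 0.0956).

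A total of 9 lists passed as higher at day 15, none of which held with an estimated correlation, and 1 of their members, Eng, was called. The corpus luteum list had a median of 0.54 and 0 of 16 members called, against 2 higher and 1 lower adjusted over the list alone (adjusted p = 0.000362, and adjusted p = 0.165 with an estimated correlation). The steroid hormone synthesis list had a median of 0.40, with 0 of 16 called and 3 higher adjusted over the list alone (adjusted p = 1.91e-06, and adjusted p = 0.0876 with an estimated correlation). The cholesterol synthesis list had a median of 0.42, with 0 of 23 called and 2 higher adjusted over the list alone (adjusted p = 5.16e-10, and adjusted p = 0.156 with an estimated correlation). The interferon response list had a median of 0.46, with 0 of 22 called and 8 higher adjusted over the list alone (adjusted p = 1.53e-10, and adjusted p = 0.120 with an estimated correlation). Its most changed member Irf7, an interferon-induced transcription factor, stood at 16.8 ± 3.58 CPM in control and 29.4 ± 6.52 CPM at day 15 (adjusted p = 0.0882). The endothelium list had a median of 0.23 and 1 of 16 members called over all genes and adjusted over the list alone (adjusted p = 0.00108, and adjusted p = 0.122 with an estimated correlation). That member was Eng, a TGF-beta coreceptor of vessels (0.49 ± 0.11). The NRF2 target list (median 0.13), the extracellular matrix list (0.16), the smooth muscle and pericyte list (0.22) and the oxidative phosphorylation list (0.11) passed with 0 members called, over all genes and adjusted over the list alone. Their adjusted p values were 0.0359, 0.0260, 0.0168 and 0.0376, and 0.297, 0.625, 0.625 and 0.698 as adjusted p with an estimated correlation. The NRF2 call ended without control 1 or 2 or day 15 library 1 or 2 (adjusted p 0.0647 to 0.122), without the 5 libraries with high Ovgp1 (0.307), with Ovgp1 as a covariate (0.109) and with the length covariate (0.0550), and the matrix call without control 2 or 4 or day 15 library 1, 2 or 3 (0.0623 to 0.161). The smooth muscle call ended without control 2, 4 or 5 or day 15 library 2 (0.0715 to 0.185), and the oxidative phosphorylation call without control 1 or 3 or day 15 library 2, 3, 4 or 5 (0.058 to 0.375). The oxidative phosphorylation call was also lost with upper-quartile normalization (0.0693) and with Ovgp1 as a covariate (0.349), and camera turned to lower without the 5 libraries with high Ovgp1 (median −0.00104, adjusted p = 0.837). The Eng call ended without control 1, 2, 3 or 5, day 15 library 1, 2 or 3 or day 30 library 3, 4 or 5 (0.0542 to 0.117). It also ended with upper-quartile normalization (0.0517), with no filter on low counts (0.0548), with only the compared groups (0.0983) and with Ovgp1 as a covariate (0.0895).

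The largest falls under the naming rule at day 15, beside Zp2 and Nlrp5, were Tmem232 (log2 fold −6.23 ± 1.25) and Ttc34 (−4.18 ± 0.96). Their control SD was above the mean, at 7.21 ± 7.63 and 5.44 ± 6.62 CPM. Without the 5 libraries with Ovgp1 above 100 CPM, their log2 folds were −4.22 ± 1.14 and −2.56 ± 0.87 (adjusted p = 0.332 and 0.478). Those of Zp2 and Nlrp5 were then −3.57 ± 0.79 and −3.32 ± 0.73 (adjusted p = 0.250 and 0.242). The oviduct epithelium list passed as lower with a median of −2.43 and a mean of −2.47. It had 0 of 16 members called and 7 lower adjusted over the list alone (adjusted p = 1.17e-05, and adjusted p = 0.419 with an estimated correlation). The call was lost with limma-voom (median −0.64, adjusted p = 0.0960), and without the 5 libraries with Ovgp1 above 100 CPM the median was 0.08 (adjusted p = 0.993). The largest rises were Entpd7, a nucleotide phosphatase gene (0.65 ± 0.14), Efhd1, which encodes a calcium-binding protein of mitochondria (0.65 ± 0.14), Eng, and the tetraspanin gene Cd151 (0.44 ± 0.10). The calls of these genes were lost on leaving out some single libraries, with adjusted p up to 0.0958 for Entpd7, 0.0936 for Efhd1, 0.105 for Cd151, 0.0937 for Tmem232 and 0.152 for Ttc34. The libraries were control 2, 3, 4 or 5, day 15 library 1, 2 or 3 or day 30 library 3 or 4 for Entpd7, control 1, 2 or 3 or day 15 library 2 or 3 for Efhd1, and control 2, 3 or 5 or day 15 library 1, 2, 3 or 4 for Cd151. They were control 2 or 3 or day 15 library 1, 2, 3 or 5 for Tmem232, and control 1, 2, 3 or 5, any day 15 library or day 30 library 3 or 4 for Ttc34. Entpd7 and Cd151 also lost their calls with no filter (adjusted p = 0.0740 and 0.0792). With only the compared groups Entpd7 (0.102), Cd151 (0.0762) and Efhd1 (0.0795) did, as with Ovgp1 as a covariate (0.0780, 0.0703 and 0.0586). From FPKM Entpd7 (0.0877 and 0.0760) and Ttc34 (0.0571 and 0.206) did, and Ttc34 with limma-voom (0.109) and at a mean of at least 1 CPM (0.0578).

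The other 15 lists did not pass at day 15, with adjusted p from 0.0641 to 0.902. Among them were p53 targets (median 0.21, adjusted p = 0.0866), apoptosis machinery (0.04, 0.649) and epoxide and glutathione detoxification (0.03, 0.565). None of the members of these 3 lists was called. The p53 target Cdkn1a (0.51 ± 0.36, adjusted p = 0.643), the epoxide hydrolase gene Ephx1 (0.26 ± 0.19, 0.655), the cholesterol carrier Star (0.73 ± 0.34, 0.414) and the androgen enzyme gene Cyp17a1 (0.84 ± 0.68, 0.705) were not called. In the red blood cell list (median 0.86, adjusted p = 0.291), the glycolytic enzyme gene Bpgm fell (−0.83 ± 0.14), a call lost without day 15 library 3 (0.0509). Median, mean and test differed in sign for ovulatory response (−0.05, −0.17, higher), detoxification (0.03, −0.12, higher), neutrophil (0.08, −0.77, lower), inflammatory cytokine (−0.09, 0.07, higher) and surface epithelium (0.12, −0.04, higher).

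Of the 175 genes, 145 changed at least 2-fold, 143 of them lower, and 2074 genes had an unadjusted p under 0.05. The values of the groups did not overlap for 531 genes, 3.04% of those tested against 0.794% by chance. The count was 36 without day 15 library 2, 46 without library 3, 80 without library 1, 49 without control 3, 50 without control 2 and 116 without control 5. It was 563 with DESeq2, 578 with limma-voom, 322 and 370 from the FPKM values, and 355 with the length covariate. Without the 5 libraries with high Ovgp1, which left 2 controls, 1 gene was called, Slc18a2. Gdf9 then had a log2 fold of −2.57 ± 0.47 and Nobox of −3.37 ± 0.63 (adjusted p = 0.154 for each), and the oocyte list a median of −2.52 with all 25 tested members below 0. With a replicate block the count was 38. The calls of Zp2 (log2 fold −3.75 ± 0.77, adjusted p = 0.0714), Zp3 (−3.04 ± 0.76, 0.126), Nlrp5 (−3.81 ± 0.70, 0.0560), Bub1b (−0.72 ± 0.14, 0.0632), Eng (0.48 ± 0.11, 0.110), Entpd7 (0.65 ± 0.15, 0.116), Efhd1 (0.65 ± 0.14, 0.0825), Cd151 (0.44 ± 0.10, 0.0999), Tmem232 (−5.81 ± 1.29, 0.0916) and Ttc34 (−3.67 ± 0.98, 0.162) were then lost. Of the 17 named genes called at day 15, 1 kept its call in all settings. Over all alternatives the adjusted p of Gdf9 ran from 2.31e-11 to 0.154 and that of Nobox from 2.46e-12 to 0.154.

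The second comparison asked how ovaries named for day 30 differed from control. The oocyte and cell cycle lists were lower, also with an estimated correlation (adjusted p = 0.0226 for each). The granulosa cell list was lower and the cholesterol and steroid hormone synthesis lists were higher, calls lost with an estimated correlation (adjusted p = 0.258, 0.0992 and 0.0992). Gdf9 fell to 1.89 ± 0.918 CPM (log2 fold −5.20 ± 0.44, adjusted p = 6.29e-07) and Amh to 9.19 ± 5.51 CPM (−4.21 ± 0.43, adjusted p = 3.35e-06). Cyp17a1, the enzyme that makes androgens (ENSMUSG00000003555, chromosome 19, 46667165 to 46672974, minus strand), rose from 218 ± 192 to 2067 ± 706 CPM (3.25 ± 0.74, n = 5 and 5, adjusted p = 0.00437). Ephx1, the microsomal epoxide hydrolase (ENSMUSG00000038776, chromosome 1, 180976210 to 181020904, minus strand), rose from 184 ± 43.9 to 521 ± 97.3 CPM (1.5 ± 0.19, adjusted p = 2.93e-05). In all, 3987 genes were called, of which 2348 were lower and 1639 higher.

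All 24 tested oocyte genes were called lower, over all genes and adjusted over the list alone, with a median log2 fold of −6.44. With the 1 member that had no count at day 30 set at its bound of 3 counts, the median was −6.37. Camera passed the list (adjusted p = 7.64e-48, and adjusted p = 0.0226 with an estimated correlation). Zp3 fell by 6.39 on the log2 scale, to 0.524 ± 0.705 CPM, and Rfpl4, an oocyte-specific ret finger protein-like gene, by 7.46. Among the largest falls were other genes with few counts left at day 30. Summed over 5 libraries, Oog3 had 2 counts, a control level 728 times higher (95% interval 201 to 6017). Trim75, Fbxw28 and Nlrp9a had 1 count each, with ratios of 717 (128 to 28375), 736 (132 to 29094) and 583 (104 to 23059). The small-follicle germ cell list had 9 of 10 members lower and 1 higher, over all genes and adjusted over the list alone. Its median was −3.15 (adjusted p = 2.93e-10, and adjusted p = 0.0596 with an estimated correlation). Nobox fell by 6.91, Elavl2 by 3.17 and Ddx4 by 2.10 on the log2 scale. The higher member was Kit, a receptor that theca and interstitial cells also express, at 76.4 ± 20.5 CPM in control and 143 ± 56.0 CPM at day 30.

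The granulosa cell list had 15 of 25 members lower and 1 higher, and 17 lower and 1 higher when adjusted over the list alone. Its median was −1.75 (adjusted p = 4.06e-09, and adjusted p = 0.258 with an estimated correlation). Esr2, the estrogen receptor of granulosa cells, fell from 91.9 ± 21.6 to 13.2 ± 1.35 CPM (−2.80 ± 0.23), and Fshr fell from 32.8 ± 18.1 to 4.91 ± 1.98 CPM (−2.74 ± 0.50). Cyp19a1 was not called (−0.64 ± 0.82, adjusted p = 0.630). The cell cycle list had 29 of 30 members lower, over all genes and adjusted over the list alone, with a median of −2.30 (adjusted p = 7.06e-54, and adjusted p = 0.0226 with an estimated correlation). The mitotic kinase genes Bub1 (−3.28 ± 0.20) and Bub1b (−2.35 ± 0.16) were examples. The DNA repair list had 15 of 25 members lower, and 16 adjusted over the list alone. Its median was −0.44 (adjusted p = 1.14e-07, and adjusted p = 0.0992 with an estimated correlation). Brca1 (−1.89 ± 0.19) and Brca2 (−1.42 ± 0.15), both of homologous recombination, were examples. Without the 5 libraries with high Ovgp1, the medians were −6.23 for oocyte, −1.95 for granulosa cell and −2.52 for cell cycle genes.

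The cholesterol synthesis list had 15 of 23 members higher and none lower, and 21 higher adjusted over the list alone. Its median was 0.84 (adjusted p = 1.22e-13, and adjusted p = 0.0992 with an estimated correlation). The sterol reductase gene Tm7sf2 rose from 13.6 ± 3.77 to 66.5 ± 16.6 CPM (2.29 ± 0.22) and the lanosterol demethylase gene Cyp51 from 118 ± 27.5 to 334 ± 59.1 CPM (1.51 ± 0.20). The steroid hormone synthesis list had 10 of 16 members higher and 1 lower, and 12 and 1 adjusted over the list alone. Its median was 0.75 (adjusted p = 7.51e-06, and adjusted p = 0.0992 with an estimated correlation). The rise of its score over that of cell type lists was 0.32 ± 0.17 for theca cell, 0.26 ± 0.19 for endothelium and 0.19 ± 0.25 for corpus luteum (SE, n = 5 and 5, exact two-sided permutation p = 0.0952, 0.214 and 0.460). It was 0.89 ± 0.25 for extracellular matrix, 0.94 ± 0.42 for smooth muscle and pericyte, 0.71 ± 0.32 for lymphocyte and 0.55 ± 0.26 for macrophage (exact permutation p = 0.00794, 0.0476, 0.0635 and 0.0873). The corpus luteum list shares Star, Cyp11a1, Hsd3b1, Hsd17b7 and Scarb1 with the steroid list, and the theca cell list shares Cyp17a1. Shared members pull these differences toward 0 whatever the cause. Cyp11a1, which makes pregnenolone from cholesterol, rose from 4216 ± 663 to 10796 ± 907 CPM (1.36 ± 0.16), and Por, the electron donor of such enzymes, rose by 0.80 ± 0.13 in log2. Star rose from 543 ± 255 to 1212 ± 178 CPM (1.16 ± 0.34, adjusted p = 0.0213), a call lost without control 2 (0.0524) or control 3 (0.0548). It was also lost without the 5 libraries with high Ovgp1 (log2 fold 0.74 ± 0.46, adjusted p = 0.353) and with Ovgp1 as a covariate (1.05 ± 0.36, adjusted p = 0.0511). The corpus luteum list had 8 of 16 members higher and 1 lower, over all genes and adjusted over the list alone. Its median was 0.45 (adjusted p = 0.00749, and adjusted p = 0.276 with an estimated correlation). The drug efflux pump gene Abcb1b rose from 468 ± 144 to 2478 ± 632 CPM (2.40 ± 0.36). The theca cell list did not pass (median 0.37, adjusted p = 0.246). It had 6 of 12 members higher, such as the retinal dehydrogenase gene Aldh1a1 (1.38 ± 0.22), and 2 lower, such as the hedgehog inhibitor Hhip (−3.56 ± 0.29), over all genes and adjusted over the list alone.

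The epoxide and glutathione detoxification list had 11 of 30 members higher and 1 lower, and 13 and 2 adjusted over the list alone. Its median was 0.28 (adjusted p = 3.87e-05, and adjusted p = 0.0992 with an estimated correlation). The rise of its score over that of cell type lists was 0.00293 ± 0.13 for theca cell, −0.06 ± 0.09 for endothelium and −0.13 ± 0.23 for corpus luteum (SE, n = 5 and 5, exact two-sided permutation p = 0.984, 0.476 and 0.587). It was 0.56 ± 0.15 for extracellular matrix, 0.62 ± 0.32 for smooth muscle and pericyte, 0.38 ± 0.21 for lymphocyte and 0.22 ± 0.20 for macrophage (exact permutation p = 0.00794, 0.0873, 0.103 and 0.302). Beside Ephx1, Ggt5, which cleaves glutathione conjugates (1.18 ± 0.13), and the glutathione transferase gene Gstk1 (1.13 ± 0.14) rose. The NRF2 target list had 8 of 22 members higher and none lower, and 10 higher adjusted over the list alone. Its median was 0.28 (adjusted p = 0.00205, and adjusted p = 0.131 with an estimated correlation), with Osgin1, an oxidative stress response gene (1.32 ± 0.28), and the pentose phosphate enzyme gene Taldo1 (0.66 ± 0.13) as examples. The endothelium list had 9 of 16 members higher, over all genes and adjusted over the list alone. Its median was 0.49 (adjusted p = 0.000145, and adjusted p = 0.0937 with an estimated correlation), with the vessel transcription factor gene Erg (0.74 ± 0.15) as an example. The interferon response list had 10 of 22 members higher, over all genes and adjusted over the list alone. Its median was 0.52 (adjusted p = 3.03e-05, and adjusted p = 0.314 with an estimated correlation), with the interferon signal transducers Stat2 (0.73 ± 0.14) and Irf9 (0.47 ± 0.09) as examples. The oxidative phosphorylation list had 6 of 23 members higher, over all genes and adjusted over the list alone. Its median was 0.22 (adjusted p = 0.00205, and adjusted p = 0.485 with an estimated correlation), with the respiratory subunit genes Ndufa1 (1.38 ± 0.24) and Sdha (0.49 ± 0.12) as examples. The calls of Osgin1 (log2 fold 1.00 ± 0.36, adjusted p = 0.102), Taldo1 (0.43 ± 0.18, 0.154), Erg (0.81 ± 0.25, 0.0546), Stat2 (0.62 ± 0.19, 0.0547), Irf9 (0.48 ± 0.15, 0.0539) and Sdha (0.52 ± 0.18, 0.0958) were lost without the 5 libraries with high Ovgp1.

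The largest rises under the naming rule were Atp12a, a proton and potassium pump subunit gene, from 3.22 ± 3.87 to 170 ± 89.7 CPM (5.72 ± 0.73), the cartilage proteoglycan gene Acan (4.08 ± 0.35), Hsd3b6, a steroid dehydrogenase gene (3.74 ± 0.84), and Cyp17a1. Without the 5 libraries with high Ovgp1, the Hsd3b6 call was lost (2.60 ± 0.85, adjusted p = 0.0709), 1 of 22 calls of named genes lost in that setting at day 30. The oviduct epithelium list passed as lower, with 8 of 16 members lower and 10 adjusted over the list alone. Its median was −2.78 (adjusted p = 0.0144, and adjusted p = 0.698 with an estimated correlation). Its call was lost without control 1, at a median of −1.63 (0.122), and without the 5 libraries with high Ovgp1, at a median of −0.63 (0.391). With Ovgp1 as a covariate it was lost too, at a median of −0.78 (0.349).

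The other lists did not pass at day 30. Those with a positive median were KIT-PI3K-FOXO3 follicle activation (0.16, adjusted p = 0.435), macrophage (0.19, 0.104), surface epithelium and mesothelium (0.32, 0.116), red blood cell (0.15, 0.912) and circadian clock (0.12, 0.364). Those with a negative median were ovulatory response (−0.82, 0.205), p53 targets (−0.09, 0.803), smooth muscle and pericyte (−0.41, 0.717), neutrophil (−1.59, 0.435), inflammatory cytokine (−0.34, 0.545) and immediate early (−0.45, 0.291). For apoptosis machinery (median −0.001, mean 0.06, adjusted p = 0.545), extracellular matrix (−0.01, −0.17, 0.902), lymphocyte (−0.07, −0.06, 0.744) and adipocyte (−1.04, −0.82, 0.902) camera pointed higher, in contrast to the median or mean. For the red blood cell list the mean was −0.08 and camera pointed lower. Single members of these lists were called. Foxo1, a transcription factor of the insulin pathway, fell from 375 ± 85.3 to 116 ± 26.7 CPM (−1.69 ± 0.21), and the complement gene C1qa rose (0.82 ± 0.18). The matrix genes Thbs1 (−1.40 ± 0.17) and Mmp2 (0.89 ± 0.15) changed in opposite directions. The nitric oxide synthase gene Nos2 fell by 2.49 and the stress gene Sesn2 rose by 0.98 in log2, while Cdkn1a was not called (−0.60 ± 0.36, adjusted p = 0.260).

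Of the 3987 genes, 1809 changed at least 2-fold, 1392 of them lower and 417 higher, and 6091 genes had an unadjusted p under 0.05. The groups did not overlap for 3003 genes, 17.2% against 0.794% by chance. The count was 1981 without the 5 libraries with high Ovgp1 and 6829 with limma-voom.

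**Figure D2:**
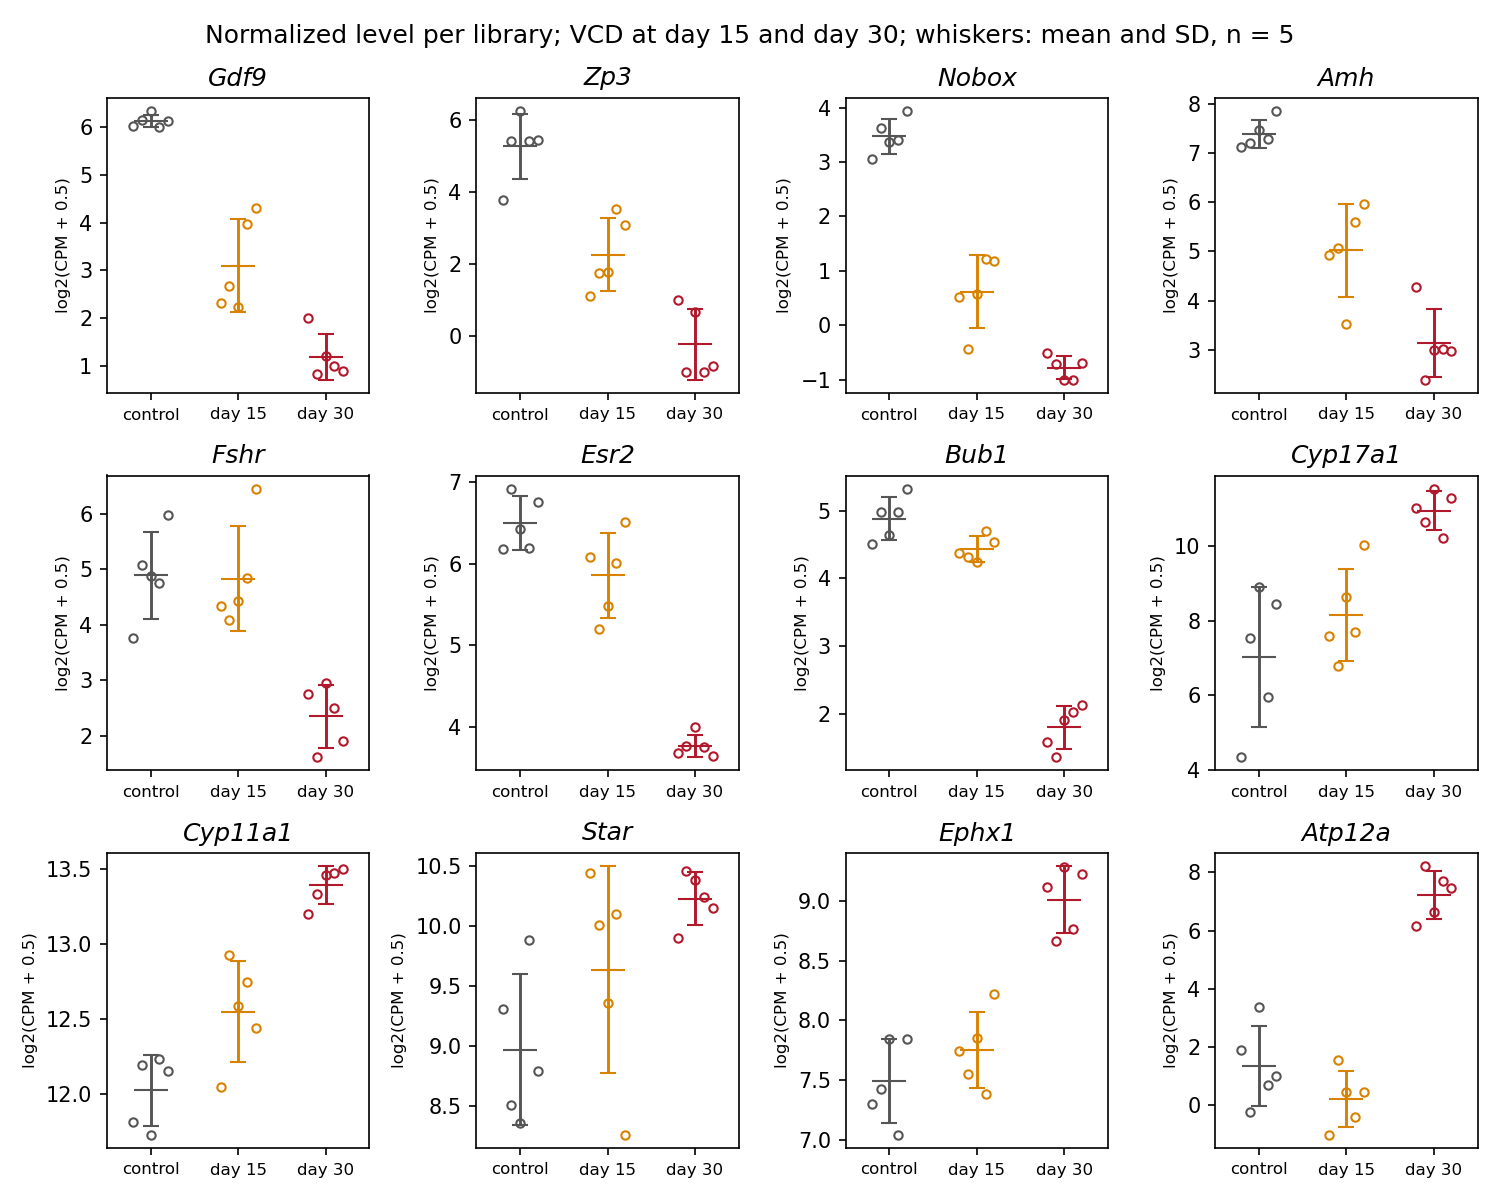
Each panel plots 1 gene, with a point per library as log2(CPM + 0.5) and the mean and SD of each group (n = 5). Gdf9, Zp3, Nobox and Amh are lower at day 15 and lower again at day 30, Fshr, Esr2 and Bub1 are lower at day 30, and Cyp17a1, Cyp11a1, Star, Ephx1 and Atp12a are higher at day 30. The vertical axes do not start at 0 and differ between panels.

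**Figure D3:**
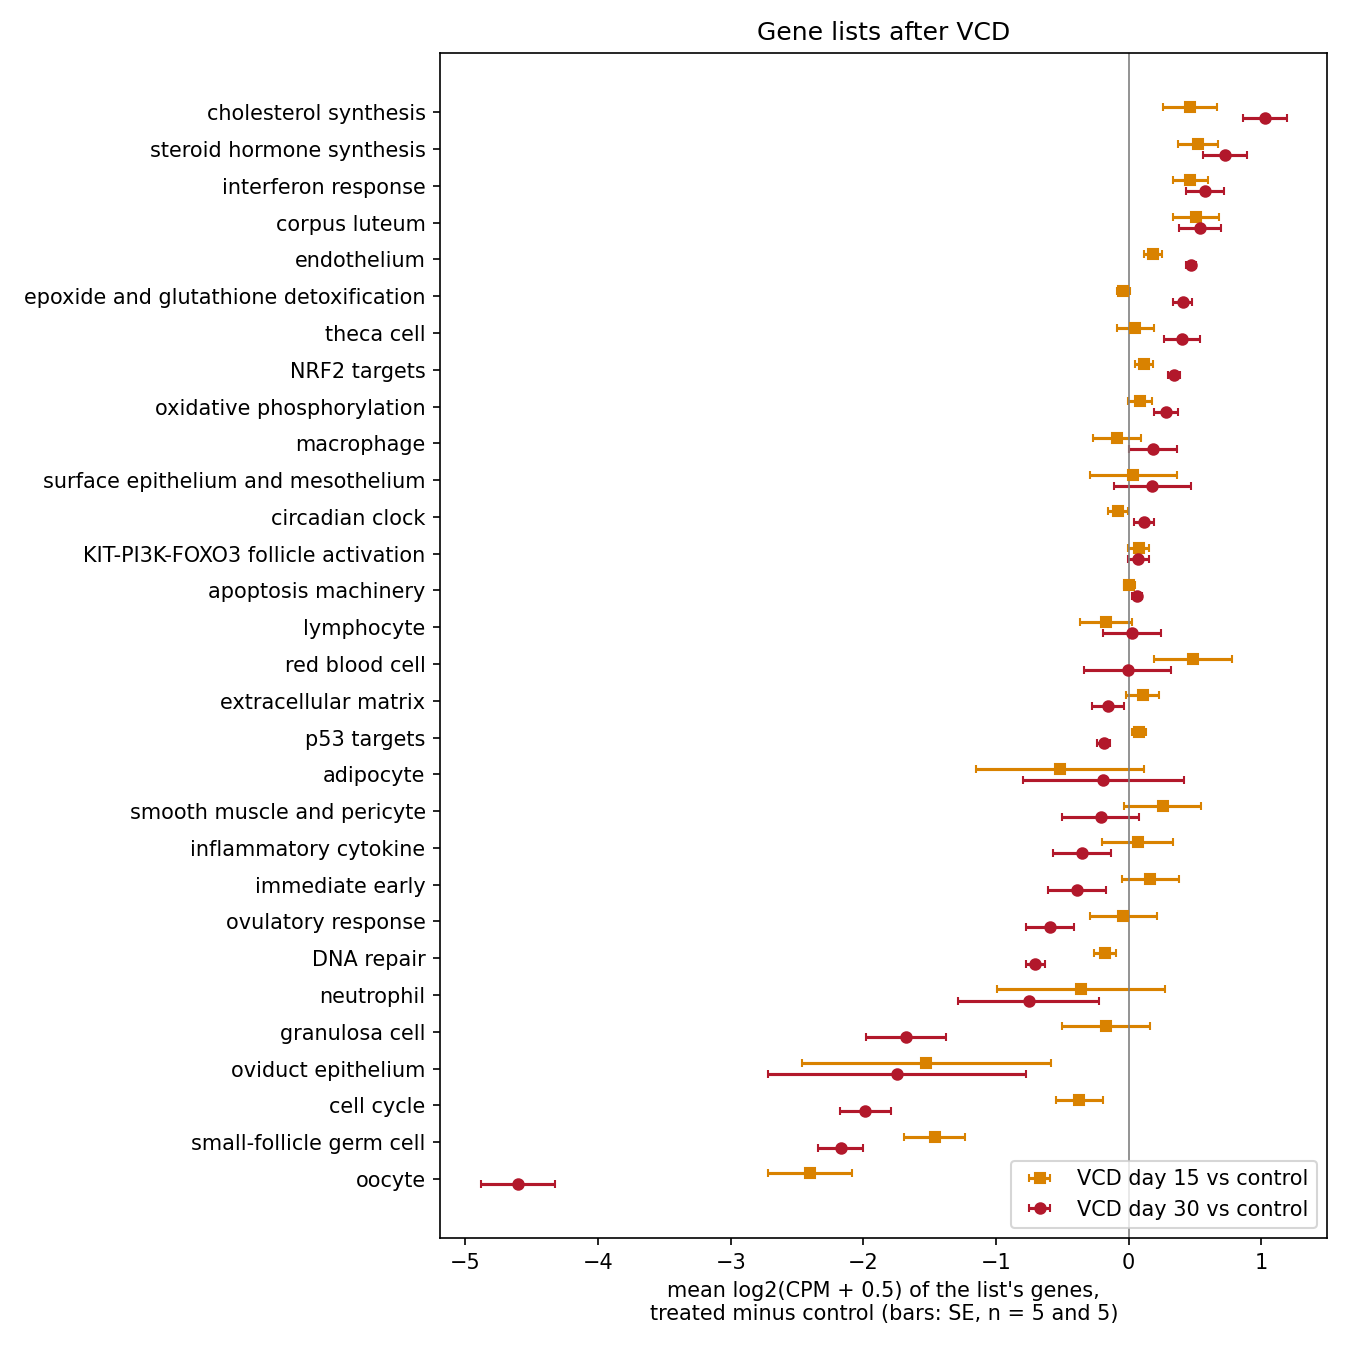
Each row of marks is 1 of the 30 gene lists. The horizontal axis is the difference in the mean log2(CPM + 0.5) of the list's genes between VCD and control, with SE (n = 5 and 5), for day 15 (squares) and day 30 (circles). The oocyte list lies at −2.40 at day 15 and −4.60 at day 30, and the cholesterol synthesis list at 0.46 and 1.03.

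The third comparison set day 30 directly against day 15, to test the difference between the named days itself. The cell cycle list was lower at day 30 than at day 15, also with an estimated correlation (adjusted p = 0.0226). The granulosa cell and oocyte lists were lower too, calls lost with an estimated correlation (adjusted p = 0.258 and 0.0849). Nr5a2, a nuclear receptor of granulosa and luteal cells (ENSMUSG00000026398, chromosome 1, 136842571 to 136960448, minus strand), fell from 486 ± 91.2 to 55.1 ± 35.9 CPM (log2 fold −3.14 ± 0.34, n = 5 and 5, adjusted p = 1.68e-05). Top2a, the topoisomerase of dividing cells, fell from 139 ± 27.7 to 25.4 ± 5.01 CPM (−2.45 ± 0.19). Atp12a rose from 0.892 ± 0.949 to 170 ± 89.7 CPM (7.52 ± 0.83). In all, 2298 genes were called, of which 1441 were lower and 857 higher.

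The oocyte list had 23 of 24 members lower, over all genes and adjusted over the list alone, with a median of −3.82, or −3.73 with the member without counts at its bound (adjusted p = 1.96e-30, and adjusted p = 0.0849 with an estimated correlation). Gdf9 fell by a further 2.38 ± 0.41 and Zp3 by 3.37 ± 0.81 on the log2 scale. The small-follicle germ cell list had 7 of 10 members lower and 1 higher, over all genes and adjusted over the list alone. Its median was −1.32 (adjusted p = 0.00115, and adjusted p = 0.251 with an estimated correlation). In it Lhx8, an oocyte homeobox gene, had 1 count at day 30, and its day 15 level was 44.2 times higher (95% interval 7.50 to 1787). Ddx4 fell by 1.18 ± 0.36 (adjusted p = 0.0414). That call was lost without control 2, 4 or 5, day 15 library 1, 2, 4 or 5 or day 30 library 2, 3, 4 or 5 (0.0528 to 0.111), without the 5 libraries with high Ovgp1 (0.0627) and with a replicate block (0.0856). The granulosa cell list had 15 of 25 members lower and 1 higher, and 17 and 3 adjusted over the list alone. Its median was −1.95 (adjusted p = 4.25e-09, and adjusted p = 0.258 with an estimated correlation). Amh fell by 2.01 ± 0.40 and Fshr by 2.82 ± 0.50, while Cyp19a1 was not called (−1.95 ± 0.84, adjusted p = 0.147). The cell cycle list had 28 of 30 members lower, and 29 adjusted over the list alone, with a median of −1.69 (adjusted p = 2.14e-56, and adjusted p = 0.0226 with an estimated correlation). The DNA repair list had 9 of 25 members lower, and 12 adjusted over the list alone, with a median of −0.32 (adjusted p = 1.10e-06, and adjusted p = 0.117 with an estimated correlation). The checkpoint kinase gene Chek1 (−3.05 ± 0.44) was an example.

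The cholesterol synthesis list had 9 of 23 members higher, and 13 adjusted over the list alone, with a median of 0.61 (adjusted p = 1.83e-07, and adjusted p = 0.251 with an estimated correlation). Tm7sf2 (1.42 ± 0.22) and Fdft1, the squalene synthase gene (0.86 ± 0.16), were examples. The steroid hormone synthesis list had 4 of 16 members higher and 1 lower, and 7 and 1 adjusted over the list alone, with a median of 0.41 (adjusted p = 0.0138, and adjusted p = 0.321 with an estimated correlation). Cyp11a1 rose by 0.82 ± 0.16 and Cyp17a1 by 2.41 ± 0.71 (adjusted p = 0.0338), whereas Star was not called (0.43 ± 0.34, adjusted p = 0.463). The Cyp17a1 call was lost without day 15 library 1, 2, 3 or 4 or day 30 library 3 or 5 (0.0694 to 0.0879). The epoxide and glutathione detoxification list had 9 of 30 members higher and 2 lower, and 12 and 2 adjusted over the list alone. Its median was 0.35 (adjusted p = 2.06e-06, and adjusted p = 0.0876 with an estimated correlation), with Ephx1 at 1.25 ± 0.19 and Ggt5 at 1.27 ± 0.13. The NRF2 target list had 2 of 22 members higher, and 4 higher and 1 lower adjusted over the list alone. Its median was 0.21 (adjusted p = 0.0163, and adjusted p = 0.251 with an estimated correlation), a call lost without day 15 library 5 (0.0658).

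The endothelium list had 2 of 16 members higher, over all genes and adjusted over the list alone, with a median of 0.34 (adjusted p = 0.0138, and adjusted p = 0.247 with an estimated correlation). The macrophage list had 5 of 18 members higher, over all genes and adjusted over the list alone. Its median was 0.21 (adjusted p = 0.0168, and adjusted p = 0.607 with an estimated correlation), with the efferocytosis receptor gene Mertk (0.65 ± 0.14) as an example. The oxidative phosphorylation list had 2 of 23 members higher, over all genes and adjusted over the list alone, with a median of 0.19 (adjusted p = 0.0151, and adjusted p = 0.625 with an estimated correlation). The macrophage call was lost without day 15 library 1 (0.0822) or day 30 library 2 (0.0841), and the oxidative phosphorylation call without day 15 library 1 (0.0972) or day 30 library 1 (0.0624). Both were also lost with limma-voom (0.0846 and 0.0924). The immediate early list had 4 of 17 members lower, and 6 adjusted over the list alone, with a median of −0.76 (adjusted p = 0.0101, and adjusted p = 0.435 with an estimated correlation). Egr1 (−1.23 ± 0.29) and the phosphatase gene Dusp1 (−1.29 ± 0.31) were examples. For the corpus luteum list, which did not pass, the median was −0.04 and the mean −0.15 while camera pointed higher (adjusted p = 0.291). The same held for KIT-PI3K-FOXO3 follicle activation (−0.04, −0.02, 0.914). The other 15 lists did not pass either, with adjusted p from 0.0507 to 0.706, and their median, mean and test shared a sign.

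Beside Atp12a, the largest rises were the mucin gene Muc5b (4.39 ± 0.74), Acan (4.35 ± 0.35) and Hsd3b6 (3.54 ± 0.83). The falls chosen under the naming rule, by fitted fold, included the tight junction gene Cldn18 with 3 counts at day 30, a day 15 level 167 times higher (95% interval 56.9 to 814), and Trim75 with 1 count (197, 34.9 to 7829). Kcnj16, a potassium channel gene (−7.07 ± 1.37), and Bhmt, a methyltransferase gene of methionine metabolism (−6.91 ± 1.12), were the others. The intervals are too wide to rank these falls, and Fbxw28 (173, 30.7 to 6893) and Nlrp9a (144, 25.5 to 5744), with 1 count each, had ratios of similar size. Bhmt stood at 73.5 ± 60.2 CPM in control, 154 ± 114 CPM at day 15 and 1.28 ± 0.457 CPM at day 30. Cdkn1a was not called (−1.11 ± 0.36, adjusted p = 0.0545). Of the 2298 genes, 1072 changed at least 2-fold, 821 of them lower, and 4601 had an unadjusted p under 0.05. The groups did not overlap for 2060 genes, 11.8% against 0.794% by chance. The count was 5258 with limma-voom and 3479 with the length covariate.

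The comparisons against control were also set side by side. Of the 175 genes called at day 15, 163 were called in the same direction at day 30, 155 lower and 8 higher. Independent lists of these sizes would share 22.3 lower and 0.845 higher genes, and 20 simulations of unchanged groups against the same controls shared none (highest 0). With no gene changed, few are called at all, so that 0 does not measure the overlap that shared controls add. Grik3, a glutamate receptor gene, was called in opposite directions (−0.89 at day 15 and 0.59 at day 30) and was chosen after its values were seen. Across the 17462 genes, which are not independent replicates, the log2 folds had a Pearson r of 0.679 and a Spearman rho of 0.543. The simulated shared controls gave a median r of 0.503. Genes were drawn independently there, without the oviduct or length differences between libraries. The covariance was 0.475 against a simulated 0.0701, a difference of 0.405. It was larger with no filter on low counts and smaller from log2(FPKM + 1), as given below, and the simulation used the main setting only. With the 5 controls split between the comparisons, the median was 36 shared calls (11 to 227 over 20 splits), the median r 0.447 (0.102 to 0.543) and the median covariance 0.574. Of all 15 libraries, leaving out 1 gave 34 shared calls without day 15 library 2, 45 without library 3, 77 without library 1 and 47 without control 2 or without control 3. Without the 5 libraries with high Ovgp1 there was 1. The count was 38 with a replicate block, 486 with DESeq2, 545 with limma-voom, 307 and 355 from the FPKM values and 323 with the length covariate.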

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

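The tests of the oviduct, cholesterol and gene length patterns, and the alternatives behind them, were chosen only after the result was seen, whereas the counts over other splits of the libraries were planned.

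A library was singled out where its gap to the nearest of the 5 libraries of its group, divided by their range, was above Dixon's 95% value of 0.71. For genes, gap and range were taken on log2(CPM + 0.5), so these ratios do not follow directly from the printed CPM. For lists the score was used, and for the total count and mitochondrial share the values as printed. If values were independent and normal, chance would put 23.85 of 477 groups of values above 0.71. The genes and lists share libraries, and many genes were named for their values, so no excess can be read from the count. It was 37, and 8 of the 37 were in VCD day 30 library 1. In that library the total count was 15021246 against 17480626 to 18035127 (ratio 0.816) and the mitochondrial share 7.97% against 3.93% to 4.84% (0.775). Its Me1 (0.742), Nusap1 (0.760), Pecam1 (0.799), Taldo1 (0.757), Egfl7 (0.842) and KIT-PI3K-FOXO3 list (0.742) also stood apart. In VCD day 30 library 2 the ratios were 0.731 for Cox5a, 0.882 for Dnah5, 0.740 for Tmem232, 0.791 for the ovulatory response list, 0.881 for the smooth muscle list and 0.867 for the oviduct list. VCD day 30 library 3 had 73.7 CPM of Cyp19a1 against 3.83 to 8.17 (0.756) and 119 CPM of Nr5a2 against 35.8 to 44.7 (0.818). Its Hhip (0.816), Bak1 (0.797) and steroid hormone list (0.816) also stood apart.

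At day 15, library 1 stood apart in Entpd7 (0.766), Casp9 (0.750), Cldn18 (0.741) and the oxidative phosphorylation list (0.858). Library 3 did so in Ddx4 (0.726), the interferon list (0.760) and the oviduct list (0.771), and library 4 in Oog3 (0.724). Control 1 was low in Zp2, with 28.9 CPM against 74.6 to 107 (0.723), and in the germ cell list (0.743). Control 2 stood apart in Entpd7 (0.750) and Esam (0.753), control 3 in Ccl2 (0.772), the p53 list (0.750) and the DNA repair list (0.769), and control 4 in Col4a2 (0.825) and Eng (0.713).

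The VCD groups named for day 30 and day 15 differed in the direct test for 2298 genes, 13 lists and 62 of the 102 named genes with an effect tested against control. These differences also hold any difference in age or in time since the last injection, which no test separated. The list medians of the difference, day 30 minus day 15 in log2, were −3.82 for oocyte, −1.32 for small-follicle germ cell, −1.95 for granulosa cell, −0.32 for DNA repair, −1.69 for cell cycle and −0.76 for immediate early. They were 0.41 for steroid hormone synthesis, 0.61 for cholesterol synthesis, 0.35 for detoxification, 0.21 for NRF2 targets, 0.34 for endothelium, 0.21 for macrophage and 0.19 for oxidative phosphorylation. Of these lists, cell cycle alone held with an estimated correlation.

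Among oocyte and germ cell genes the differences were −2.38 for Gdf9, −3.40 for Zp2, −3.37 for Zp3, −4.20 for Nlrp5, −3.68 for Nobox, −1.33 for Ooep, −6.30 for Rfpl4, −1.32 for Elavl2 and −1.18 for Ddx4. For genes with 1 or 2 counts at day 30, the ratio of day 15 to day 30 was 173 for Fbxw28 (95% interval 30.7 to 6893), 144 for Nlrp9a (25.5 to 5744), 121 for Oog3 (33.0 to 1002) and 197 for Trim75 (34.9 to 7829). Among granulosa, cell cycle and repair genes they were −2.01 for Amh, −2.82 for Fshr, −2.20 for Esr2, −1.65 for Bub1b, −2.80 for Bub1, −1.73 for Nusap1, −1.60 for Ckap2, −1.55 for Brca1 and −1.0 for Brca2. Other falls were −0.59 for Col4a2, −0.84 for Acta2, −2.23 for Cxcr2, −1.31 for Fos, −1.67 for Foxo1, −2.78 for Hhip, −1.03 for Lpl, −0.77 for Mylk, −1.56 for Nos2, −0.74 for Rgs2, −1.15 for Thbs1 and −0.42 for Tubb4b. Steroid, sterol and detoxification genes rose by 0.82 for Cyp11a1, 2.41 for Cyp17a1, 3.54 for Hsd3b6, 0.69 for Por, 1.42 for Tm7sf2, 1.01 for Cyp51, 1.25 for Ephx1, 1.27 for Ggt5, 1.00 for Gstk1 and 0.76 for Aldh1a1. Other rises were 7.52 for Atp12a, 4.35 for Acan, 2.68 for Abcb1b, 1.42 for Efhd1, 1.23 for Hlf, 1.06 for Ndufa1, 1.04 for Mmp2, 0.82 for Plin1, 0.74 for C1qa, 0.53 for C1qc, 0.69 for Sesn2, 0.55 for Bcl2l2, 0.49 for Sdha, 0.48 for Upk1b, 0.44 for Casp9, 0.39 for Esam and 0.38 for Csf1. Of 28 alternatives, Esam lost its call in 18, Ddx4 in 16, Tubb4b in 15, Cxcr2 in 14 (of 26), Plin1 in 9, Aldh1a1 and Upk1b in 8 each, Mylk in 7, Cyp17a1 and Rgs2 in 6 each and Bcl2l2 in 1. A replicate block ended those of Esam, Ddx4, Tubb4b, Cxcr2 and Rgs2.

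The fall of the oviduct epithelium list may come from oviduct tissue in some libraries. Within each of the 3 groups the library highest in Ovgp1 was also highest in the mean of the other list members (one-sided exact permutation p = 0.008, the smallest that 125 arrangements allow). Without the 5 libraries with Ovgp1 above 100 CPM, the day 30 median was −0.63 in place of −2.78, and 0 members were called. Resampling the list members gave an interval of −0.912 to −0.392, which holds no variation between mice. These libraries were chosen by Ovgp1, itself a member of the list, and controls 1, 2 and 3 were among them. Leaving them out shrinks the fall whatever its cause. The smaller median therefore cannot tell how much of the fall was an effect of VCD. None of the list's 16 members stands in another list, and 11 of them still passed the expression filter without these libraries.

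The rise of the cholesterol synthesis list at day 30 may follow from loss of follicle cells, from scaling or from oviduct tissue. If a lower share of follicle cells raised all other cell types alike, the list would rise no more than theirs. It rose over the extracellular matrix list by 1.19 ± 0.26 (SE, n = 5 and 5, exact two-sided permutation p = 0.00794). Over the other 6 lists of cell types set beside it, the rise was smallest over corpus luteum (0.49 ± 0.18, exact permutation p = 0.0397) and endothelium (0.56 ± 0.17, exact permutation p = 0.0317) and largest over smooth muscle and pericyte (1.24 ± 0.35, exact permutation p = 0.0159). For the steroid hormone synthesis and detoxification lists the same difference was 0.89 ± 0.25 and 0.56 ± 0.15 over extracellular matrix (exact permutation p = 0.00794 for each), but lay within 2 SE over corpus luteum (0.19 ± 0.25 and −0.13 ± 0.23) and endothelium (0.26 ± 0.19 and −0.06 ± 0.09), and the causes of their rise were not weighed here. The corpus luteum list shares 5 of its 16 members with the steroid list, which pulls the steroid difference toward 0. With upper-quartile scaling the median of the cholesterol list was 0.78, and without the 5 libraries with high Ovgp1 it was 0.90 with 10 members called. The median without the 5 libraries argues against oviduct tissue as the whole cause. Upper-quartile scaling moved the median log2 fold of all tested genes only from −0.0219 to −0.0773. It could not have brought a list median of 0.84 to 0, so it cannot decide on scaling as a cause. The rise did not depend on which of the 2 scalings was used, and an error common to both was not tested. The score differences argue against an equal rise of all other cell types. Since the lists set beside it did not move alike, they do not tell whether loss of follicle cells was the cause. A larger share of luteal or interstitial cells, a change within them, and a possible difference in age between groups stay open and were not tested.

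The real grouping called the most genes of the 100 splits counted in each comparison, out of 126 possible. Of the 100, only the real 1 reached 175, 3987 and 2298 genes, and the highest other splits gave 142, 2586 and 538. This argues against chance as the source of the gene counts but does not exclude it. For the numbers of lists passed at the preset correlation the splits did not argue against chance. There 10, 28 and 30 splits of 100 gave at least the real 15, 14 and 13, with highest others of 17, 18 and 20. The highest other splits point to a structure of the samples, and a candidate explanation is transcript length bias: in the day 30 split that gave 2586 genes, control 1 and VCD day 30 library 1 had changed places and log2 folds correlated with gene length at 0.275 across genes. That split called 620 genes higher among the longest genes and 78 among as many of the shortest, and the real day 30 folds correlated with length at −0.0349. With each library's length correlation as a covariate the real day 30 count was 5278, so the values argue against length bias as the cause of the real calls, of which 1022 were also called in that split.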

How the results depend on the processing

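The alternatives without the 5 libraries with Ovgp1 above 100 CPM and with a covariate for Ovgp1 or for gene length were chosen only after the result was seen. For single results, 4869 values of named genes under an alternative kept their direction and side of the threshold, 377 fell short of it, 55 newly passed, 8 moved and 0 reversed. For gene lists the numbers were 2280, 89, 71, 77 and 3. For lists the direction is that of camera. The 3 that reversed were day 15 lists without the 5 libraries, where 2 controls were left, with medians of 0.0756 for the oviduct list, −0.00104 for the oxidative phosphorylation list and 1.3 for the neutrophil list. The neutrophil median was positive in the main fit too (0.08), where camera pointed lower.

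The count at day 15 against control was 563 with DESeq2, 578 with limma-voom, 322 from log2(FPKM + 0.1), 370 from log2(FPKM + 1), 355 with the length covariate, 33 at an adjusted p under 0.01 and 1 without the 5 libraries. At day 30 against control it was 6829 with limma-voom, 1981 without the 5 libraries, 1809 for a fold of at least 2 and 2217 at an adjusted p under 0.01. For day 30 against day 15 it was 5258 with limma-voom, 3479 with the length covariate, 1072 for a fold of at least 2 and 1143 at an adjusted p under 0.01. Shared calls numbered 486 with DESeq2, 545 with limma-voom, 307 and 355 from FPKM, 323 with the length covariate, 36 with the controls split and 1 without the 5 libraries. The covariance was 1.42 with no filter on low counts and 0.0910 from log2(FPKM + 1). With an estimated correlation 2, 2 and 1 lists passed. A stricter threshold lowers a count by construction, and for the other alternatives the cause was not tested.

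Leaving out 1 library gave 36 (without day 15 library 2) to 203 genes (without control 1) at day 15, 3145 to 4437 at day 30 and 1618 to 2739 between the days. Lists numbered 10 to 16, 14 to 15 and 11 to 17, shared calls 34 to 191 and the covariance 0.423 to 0.609. The replicate block took the day 15 count from 175 to 38 and the shared calls from 163 to 38. All other alternatives run for a count left it within the bound used for calling it the same. The stricter thresholds were not applied to the shared calls.

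Over 15 pairs of libraries with the same replicate number r ran from −0.366 to 0.321, 6 were above 0.1 and 2 matched their own number best. Between control and day 15 it was 0.135, −0.0989, 0.321, 0.101 and 0.229 for numbers 1 to 5, and both pairs that matched best (3 and 5) were among these, so a pairing of these groups stays open. These r need not come from a pairing. Control 3 and day 15 library 3 both had high Ovgp1 (1932 and 848 CPM). The length correlations were 0.313 and 0.314 for number 1 and −0.166 and −0.203 for number 5. With a replicate block, 10 of the 17 named genes called at day 15 fell short of the threshold, against 5 of 69 at day 30 and 8 of 64 between the days. Over all settings together, 1 of the 17, 46 of the 69 and 45 of the 64 kept their call. The numbers that fell short without the 5 libraries with high Ovgp1 were 16, 22 and 10. At 15021246 to 18035127 counts per library, genes with few counts at day 30 allow ratios with wide intervals only.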

Other observations

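The tests of gene families below were chosen only after the result was seen. Groups of genes whose symbols share a stem were tested for an excess of called genes, with a one-sided Fisher's exact test against all 17462 tested genes. This test treats the genes of a family as independent. Its p values make no allowance for genes that move together between mice and are too small where they do. Of 1004 such tests 24 passed. At day 30 against control, 8 of 18 Aldh genes, aldehyde dehydrogenases, were higher (adjusted p = 0.00733, median log2 fold 0.52). Among them Aldh2, the mitochondrial acetaldehyde enzyme, stood at 331 CPM in control and 857 CPM at day 30 (1.37 ± 0.16), and the folate enzyme gene Aldh1l1 at 29.5 and 85.8 CPM (1.54 ± 0.21). Of 12 Irf genes 6 were higher (adjusted p = 0.0182, median 0.39), including Irf8, a transcription factor of myeloid cells, from 19.2 to 40.2 CPM (1.06 ± 0.14). Irf2bpl shares the stem and counts among the 6 but is not an interferon regulatory factor. Between the VCD groups, 9 of 31 Cyp genes were higher at day 30 (adjusted p = 0.00101, median 0.35), among them the retinoic acid hydroxylase gene Cyp26b1 (1.17 ± 0.26) and the fatty acid hydroxylase gene Cyp4f14 (1.46 ± 0.22). Of 269 Slc genes, which encode transporters, 48 were higher at day 30 than in control (adjusted p = 0.000921), with a median of 0.03 that became −0.02 with upper-quartile scaling.

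Families with an excess of lower genes at day 30 against control were Kif, kinesin motors (20 of 36, adjusted p = 2.92e-06), Mcm, the replicative helicase (8 of 10, 0.000412), Cep, centrosome proteins (14 of 36, 0.00762), Rad (9 of 18, 0.0115) and Nup, nuclear pore proteins (9 of 21, 0.0378). The families Nlrp (11 of 17, 0.000181) and Fbxw (13 of 22, 9.90e-05), each with some members in the oocyte list, and Tex (6 of 10, 0.0331), were others. Of 8 Cct genes, subunits of the chaperonin that folds actin and tubulin, 6 were lower (adjusted p = 0.00762), with a median of −0.44. An example was Cct4 at 279 CPM in control and 196 CPM at day 30 (−0.51 ± 0.09). Of 8 Tubb genes, beta-tubulins, 6 were lower at day 30 than at day 15 (adjusted p = 0.000760), among them Tubb5 (−1.23 ± 0.11). The signs of these medians held with DESeq2 size factors and upper-quartile scaling. The axonemal dynein family Dnah also had an excess (9 of 16, 0.00475), with a median of −2.49, which was −0.45 without the 5 libraries with Ovgp1 above 100 CPM. Ccdc genes had one too (28 of 110, 0.0240). Their median over all 110 was −0.17, which was −0.13 without the 5 libraries.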
